A study of Arabidopsis thaliana with 12 samples.

How the data were processed

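The measurements were 12 Affymetrix ATH1 arrays of biotin-labelled total RNA from 5 day old Arabidopsis seedlings of the Columbia background. The deposited table held an intensity per probe set and array, the linear signal of the MAS5 algorithm, per the submitters' processing notes. The version of MAS5, the detection calls and the annotation behind it were not given in the sources used here. The values themselves showed that the authors had scaled each array: with 2% of the values trimmed at each end, the mean signal was 100.01 on 11 arrays and 100.1 on the remaining array. The median signal lay between 40.7 and 44.9. Such scaling gives every array the same average, so a shift shared by most transcripts would not be seen. Scanner files were not used here.

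The array labelled Zat12 replicate 2 had 6408 empty cells, 28.1% of its probe sets, and the other 11 arrays had none. Empty cells were left empty, so means of untreated Zat12 rest on 2 arrays where that array had no value. Of the 22810 probe sets, 64 were hybridisation and labelling controls and were kept out of the tests. Of the 22746 others, 13513 were paired with exactly 1 gene in the platform annotation used here, 503 with several and 8730 with none. Gene names were updated through a RefSeq gene table of the assembly TAIR10.1, in which 13436 of the 13513 genes were found. The name of 11933 of them was only a locus number, and no coordinates were used because the table of values names no genome build. Unnamed probe sets were tested with the others, and probe sets with several genes were never named. No probe set was paired with ZAT12 in this annotation, so the level of the over-expressed gene, the usual check of the labels, was not analysed here.

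Signals were turned into log2(signal + 3), where 3 is the 10th percentile of all values. Fold changes are on that scale, which understates changes at low signal. Probe sets were tested if their mean was above the 40th percentile, a mean log2 of 4.96 or a signal of 28.1. This left 13647 probe sets, 7360 of them with 1 named gene. No further normalization was applied. limma 3.58.1 in R 4.3.3 fitted 1 linear model with the 4 groups of 3 arrays, with a mean-variance trend and 9.12 prior degrees of freedom. Its 5 contrasts were H2O2 against untreated in wildtype, the same in Zat12, Zat12 against wildtype without treatment, the same under H2O2, and the interaction, the difference between the H2O2 responses of the genotypes. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 over the 13647. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the annotation and the plots.

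The genes named were, for H2O2 in wildtype and for untreated Zat12, the 8 called probe sets with the largest change in each direction, and 5 in each direction for the other contrasts. They had to have exactly 1 gene and, apart from the interaction, groups of arrays that did not overlap, which chance alone gives in 10% of cases for 3 arrays against 3. From each gene list discussed, up to 4 members with the largest changes were added. The design, the contrasts, this rule, the alternatives and 25 gene lists with 459 genes were fixed before the data were examined. Only 77 of those 459 genes, 16.8%, had a named probe set, so 16 lists drawn from the symbols in the annotation were added before any test was run. Of these 41 lists, 29 had at least 3 tested members. List members called measured below are those with a named probe set above the filter, and other members may be on the array without a name. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the 29 lists within a contrast. The empty cells ruled out the usual form of the test, so it was run on the moderated statistics in its preranked form. An estimated correlation and the rotation test fry were computed on the 11 complete arrays. A further 3 lists were chosen after values were seen and adjusted among themselves.

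The code was tested on simulated arrays with the real means, spreads and empty cells, in which 200 of 13647 probe sets were changed per contrast. For H2O2 in wildtype it recovered 40.3% of changes of 1.5-fold, 87.3% of 2-fold and 98.4% of 4-fold. For the interaction the shares were 12.9%, 59.1% and 94.4%. False calls made up 3.7% to 6.58% of all calls. A shift of the chaperone list was called in every contrast, and the other list called each time was the heat shock list, which shares 5 members with it. The simulated probe sets varied independently of each other. The simulation therefore does not show how often lists or probe sets are called falsely when probe sets are correlated.

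Alternatives covered quantile and median scaling, the offset, the filter, the trend, fits on the compared groups only, stricter thresholds, ambiguous probe sets, the replicate number as a block and each array left out in turn. A fit without plastid-encoded probe sets and a fit with the signal of the 25S ribosomal RNA control as a covariate were added after the data were seen. The labels do not say what the replicate numbers mark. By the rule that every same-numbered pair of 2 groups deviates together, with a correlation of deviations from the group means over 0.1, the numbers paired the arrays of treated wildtype and treated Zat12 (0.122 to 0.146, against -0.0913 to -0.0346 for different numbers) and no other 2 groups. With 3 arrays per group and every 2 of the 4 groups examined, chance can meet this rule. Deviations cancel within a group, so high correlations for same numbers go with low ones for different numbers. Untreated wildtype and untreated Zat12 went the other way, at -0.254 to -0.0313 for same numbers and -0.0808 to 0.214 for different numbers. Whether the numbers mark a true pairing is therefore open. A fit of the treated arrays with the replicate number as a block was added as an alternative. Untreated and treated Zat12 missed the rule with 2 of 3 pairs over 0.1 (0.0789 to 0.232, against -0.133 to 0.0127 for different numbers). No pair of arrays shared identical values, and the highest correlation between arrays was 0.982.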

Results

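Transcript levels of wildtype Arabidopsis seedlings and of seedlings over-expressing Zat12, a zinc finger protein of the stress response, were compared with and without hydrogen peroxide. The 12 arrays fell into 4 groups of 3, namely untreated wildtype, wildtype given 20 mM H2O2 for 1 hour, untreated Zat12, and Zat12 given H2O2 in the same way. All seedlings were 5 days old and had grown in liquid culture. The labels do not say whether replicates came from separate cultures, so every p-value measures the spread between these arrays, which may be technical. The number of arrays, 3 per group, limits the precision. The first principal component held 59.2% of the variance and separated treated from untreated arrays, and the second held 9.49% and separated the genotypes.

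**Figure D1:**
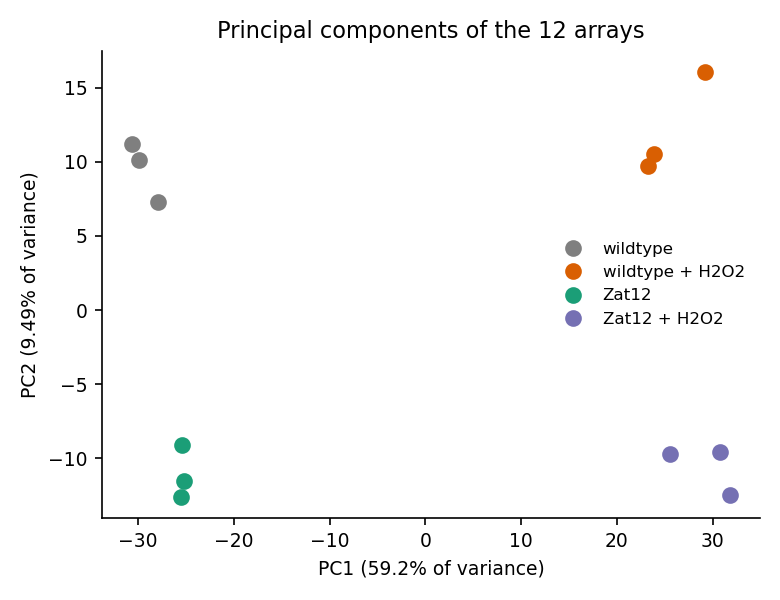
Each point is 1 array, placed by its scores on the first (x axis, 59.2% of the variance) and second (y axis, 9.49%) principal components of the log2 signals, coloured by group. Untreated arrays lie at negative and H2O2 arrays at positive scores of the first component.

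The comparison of treated with untreated wildtype asked which transcripts respond to H2O2 within 1 hour. UGT73B5 (AT2G15480), a UDP-glycosyltransferase of stress and xenobiotic responses, rose from a signal of 2.17 ± 1.12 to 485 ± 98.4, and AT1G26380, a berberine bridge enzyme-like oxidase, from 1.19 ± 0.551 to 249.5 ± 62.3 (SD, n = 3 per group). Both untreated signals lay below the offset of 3, so their fold changes are set by it and have no order; the log2 value of UGT73B5 was 7.92 with no offset and 5.12 with 4 times the offset, and AT1G26380 did not pass the filter with no offset. STZ (AT1G27730), the zinc finger repressor also called ZAT10, rose from 56.3 ± 32 to 1247 ± 59.1, and AT4G01870 from 88.2 ± 6.13 to 2701 ± 850.1 (SD, n = 3 per group). Heat shock proteins rose with them: AT1G53540, a cytosolic small heat shock protein, by 5.01 (SE 0.27) and AT5G51440, a mitochondrial one, by 4.15 (SE 0.30). Among the drops was that of AT4G26010, a class III peroxidase, with a log2 fold change of -2.01 (SE 0.27), from 292 ± 53.4 to 73.2 ± 26.5 (SD, n = 3 per group). AT2G36220 (4.15) and AT1G72900 (4.13), a protein with a TIR domain, completed the genes with the largest rises. The untreated signals of AT1G53540, AT5G51440 and AT1G72900 were 10.3, 10.8 and 7.85, so their fold changes move with the offset as well. The limma adjusted p of these 8 rises was between 3.01e-12 and 1.34e-06.

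In all, 1309 probe sets rose and 1689 fell, 22% of those tested, and by at least 2-fold 608 rose and 110 fell. Besides AT4G26010, the drops of named genes included those of AT1G75200 (-1.91), AT1G06980 (-1.64), AT3G15570 (-1.62), AT1G33055 (-1.61), AT5G44680 (-1.44), AT2G39500 (-1.44) and AT3G25930 (-1.35), with limma adjusted p between 2.26e-06 and 0.00101. With the 25S control signal as a covariate the counts were 869 and 820, and AT1G06980, AT1G33055 and AT2G39500 were no longer called (adjusted p = 0.102, 0.0963 and 0.0623). Without wildtype H2O2 replicate 1, 1074 probe sets fell.

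Of 14 chaperones and co-chaperones, which help proteins fold, 9 rose and 0 fell, or 11 and 0 adjusted over the list alone. Their median log2 fold change was 1.25 (limma's camera, adjusted p = 6.25e-11, or 0.0144 with an estimated correlation). The small heat shock protein AT5G37670 rose by 3.28 (SE 0.15), AT5G48570, an FKBP-type peptidyl-prolyl isomerase, by 3.26 (SE 0.24) and Fes1A, a co-chaperone of Hsp70, from 63.3 ± 7.54 to 435 ± 14.4 (SD, n = 3 per group). All 5 measured members of the planned heat shock list of 17 genes rose, which are also members of the chaperone list (adjusted p = 1.53e-09, or 0.01 with an estimated correlation, with 5 called adjusted over the list alone). Of 13 genes of folding and stress in the endoplasmic reticulum 2 rose and 2 fell, also adjusted over the list alone, with a median of -0.03, and that list was not called (adjusted p = 0.51).

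All 3 measured stress-related WRKY factors, of 21 in the list, rose, WRKY6 by 2.91 (SE 0.17), WRKY22 by 1.07 and WRKY53 by 1.01 (limma's camera, adjusted p = 2.52e-04, or 0.0625 with an estimated correlation, with 3 called adjusted over the list alone). Of 3 measured detoxification genes 2 rose, UGT73B5 and AER, an alkenal reductase, the latter by 2.66 (camera adjusted p = 6.75e-05; adjusted p = 0.124 with an estimated correlation; 2 adjusted over the list alone). Of 28 UDP-glycosyltransferases 6 rose, among them UGT87A2 (1.72) and UGT73B1 (1.65), and 1 fell, UGT78D1 (-1.19), a flavonol glycosyltransferase (adjusted p = 0.00904; adjusted p = 0.268 with an estimated correlation and 0.0974 with the 25S control as a covariate; 7 and 2 adjusted over the list alone). The calmodulin-like calcium sensors CML38 (2.60) and CML42 (1.68) rose, the only ones of 5 to do so (adjusted p = 0.0206; adjusted p = 0.124 with an estimated correlation, and 0.0567 without wildtype replicate 3; 2 adjusted over the list alone). Of 7 U-box ubiquitin ligases 3 rose, PUB23 (1.98), PUB24 (1.52) and PUB22 (0.62), with an adjusted p = 0.0447 for the list and 3 adjusted over the list alone. That call ended without wildtype replicate 2 (0.0703), wildtype H2O2 replicate 2 (0.0655) or Zat12 H2O2 replicate 1 (0.0511), and with the 25S control as a covariate (0.095), with which PUB22 was not called either (0.156). The same list had an adjusted p = 0.15 with an estimated correlation.

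Other lists of stress enzymes were not called. Of 4 glutathione transferases GSTU25 rose by 3.61 and GSTU22 fell, at -0.69 (limma's camera, adjusted p = 0.463; 1 and 1 adjusted over the list alone), and the list's median of -0.11 and mean of 0.67 differed in sign. Of 9 glutathione transferases of the annotation GSTU25 rose, and GSTU22 and GSTU26 (-0.61) fell (adjusted p = 0.712; 1 and 2 adjusted over the list alone), with a median of -0.06 and a mean of 0.25. Of 3 genes of sulfate assimilation the ATP sulfurylase APS3 rose by 2.59 (adjusted p = 0.124; 1 adjusted over the list alone). Among 7 measured antioxidant enzymes, of 25 in the list, the monodehydroascorbate reductase ATMDAR2 rose, from 423 ± 39.7 to 799 ± 73.6 (SD, n = 3 per group), and 6 were not called. The list itself was not called (camera of limma, adjusted p = 0.43). None of the 3 measured reference genes was called in this or any other contrast by limma, with a median log2 fold change of -0.19 here.

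**Figure D2:**
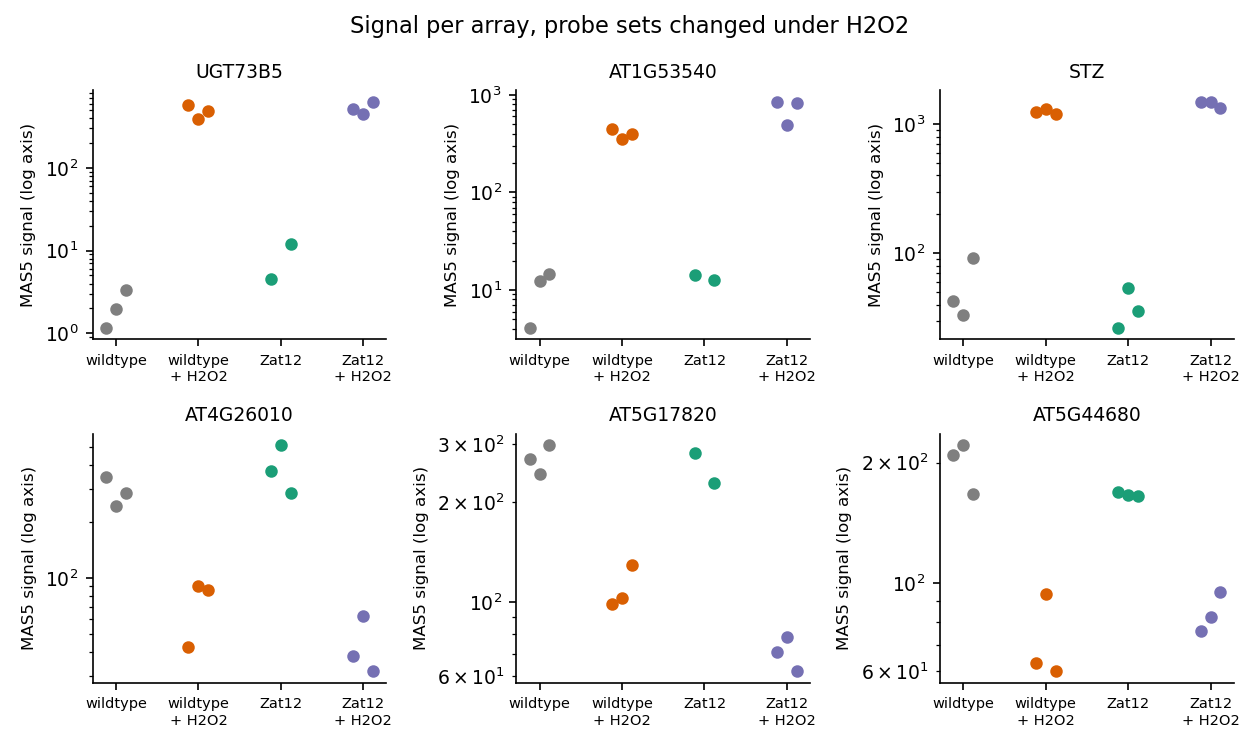
MAS5 signal (y axis, log scale, arbitrary units) of 6 genes on each array, by group (x axis); each point is 1 array, and probe sets empty on Zat12 replicate 2 have 2 points there. UGT73B5, AT1G53540 and STZ lie higher and AT4G26010, AT5G17820 and AT5G44680 lower on the treated than on the untreated arrays of each genotype.

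Transcripts encoded in the plastid genome were higher in treated than in untreated wildtype. Of 56 measured, 45 rose and 0 fell, or 50 and 0 adjusted over the list alone, with a median log2 fold change of 1.21 (limma's camera, adjusted p = 3.41e-24; adjusted p = 0.15 with an estimated correlation). The photosystem genes psaA and psbC rose by 3.42 (SE 0.45) and 3.01 (SE 0.39). The untreated wildtype arrays stood apart in this group, with a median centred log2 signal of -0.80 ± 0.37 (SD, n = 3) against 0.50 ± 0.23 in treated wildtype, 0.27 ± 0.24 in Zat12 and 0.12 ± 0.28 in treated Zat12. They also had the lowest mean signal on the control probe set for 25S ribosomal RNA, 71.4 ± 48.1 (SD, n = 3), against 232 ± 92.4, 173 ± 92.3 and 227 ± 81.9 in those groups, although wildtype replicate 3 (125.3) lay above Zat12 replicate 3 (96.3). The 3' to 5' ratio of the actin control, a sign of RNA integrity, was 6.57 ± 2.83 in untreated wildtype and between 4.85 and 5.35 on average elsewhere. Wildtype replicate 3 had the lowest actin ratio of the 12 arrays, 3.85. The same ratio of the GAPDH control did not set untreated wildtype apart, at 0.751 to 0.867 there and 0.741 to 0.866 on the other arrays. With the 25S control signal as a covariate, the median of the 56 was 0.63 and 19 were called.

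**Figure D3:**
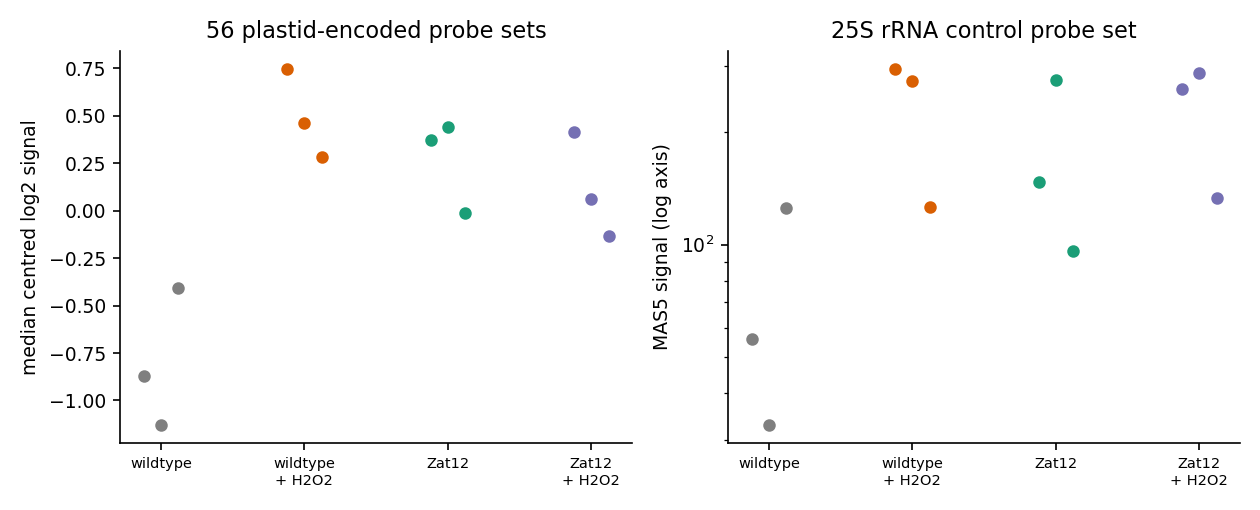
Left, the median of 56 plastid-encoded probe sets on each array (y axis, log2 signal centred per probe set); right, the signal of the 25S ribosomal RNA control (y axis, log scale, arbitrary units); x axes give the group, and each point is 1 array. The 3 untreated wildtype arrays have plastid medians between -1.13 and -0.41.

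The comparison within Zat12 seedlings asked the same question in the over-expressing line. Among the rises were genes named above for wildtype. STZ rose by 5.15 (SE 0.26), and AT1G53540 from 13.5 ± 1.05 (SD, n = 2) to 725 ± 198.7 (SD, n = 3). AT1G26380 rose from 0.848 ± 0.175 to 279 ± 72.5 and AT5G51440 from 4.49 ± 2.64 to 347 ± 45.7 (SD, n = 3 per group), and UGT73B5 from 8.23 ± 5.29 (SD, n = 2) to 535 ± 89 (SD, n = 3). At untreated signals this low the fold changes depend on the offset and have no order; the log2 value of UGT73B5 was 6.18 with no offset and 4.77 with 4 times the offset. Among the drops were those of 3 class III peroxidases, AT4G26010 at -3.08 (SE 0.27), AT1G30870 at -1.89 (SE 0.20) and AT5G17820 at -1.81 (SE 0.16), beside AT5G54370 at -2.30 (SE 0.45) and AT5G60530 at -1.84 (SE 0.37). Treated signals of these last 2 went down to 3.88 and 4.88, so they depend on the offset too and have no order, with -2.76 and -2.11 with no offset and -1.63 and -1.39 with 4 times the offset. AT4G26010 went from 391 ± 115 to 44.1 ± 16.3 (SD, n = 3 per group). The limma adjusted p of these 10 genes was between 2.69e-12 and 0.00163.

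In all 1114 probe sets rose and 1244 fell, 17.3% of those tested, and by at least 2-fold 550 rose and 114 fell. Of the 14 chaperones and co-chaperones 10 rose, also adjusted over the list alone, with a median of 1.46 (limma's camera, adjusted p = 2.67e-14; adjusted p = 0.00564 with an estimated correlation). The 5 measured members of the heat shock list rose (adjusted p = 5.9e-11; adjusted p = 0.0054 with an estimated correlation), 5 adjusted over the list alone. The 3 WRKY factors rose, led by WRKY6 at 2.44 (adjusted p = 2.75e-04; adjusted p = 0.0448 with an estimated correlation), 3 adjusted over the list alone. Of the 5 calmodulin-like genes CML38 (3.03), CML41 (0.73) and CML42 rose (adjusted p = 0.00471; adjusted p = 0.0733 with an estimated correlation), and adjusted over the list alone 3 rose and 1 fell. Of the 3 detoxification genes UGT73B5 and AER (2.52) rose (adjusted p = 6e-04; adjusted p = 0.158 with an estimated correlation), 2 adjusted over the list alone. None of the 56 plastid-encoded probe sets was called by limma, with 4 at an unadjusted p below 0.05, and 10 were called with the 25S control as a covariate.

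Without Zat12 replicate 1, 825 probe sets fell, WRKY53 (0.89) had an adjusted p of 0.0907 and CML41 one of 0.0681. WRKY53 was also not called without Zat12 replicate 3 (0.173) or Zat12 H2O2 replicates 2 (0.152) and 3 (0.091), nor CML41 without Zat12 replicate 2 (0.101) or Zat12 H2O2 replicate 3 (0.108).

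The H2O2 responses of the genotypes, which share no arrays, were closely related. Across the tested probe sets, which are not independent replicates, their log2 fold changes had r = 0.852 and a covariance of 0.278, beside simulated values of -5.8e-04 and -2.06e-05 for unchanged groups. In both genotypes 920 probe sets rose and 736 fell, where independent lists of these sizes would share 107 and 154, and 1 went in opposite directions.

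The comparison of untreated Zat12 with untreated wildtype asked what over-expression changes on its own. CCS (AT1G12520), the copper chaperone that loads superoxide dismutase, was higher in Zat12, with a signal of 450 ± 33.3 against 115 ± 11.9 (SD, n = 3 per group) and a log2 difference of 1.94 (SE 0.13, limma adjusted p = 1.09e-07). AT2G04050, a MATE-type efflux carrier, was higher by 2.37 (SE 0.44). With the 25S control as a covariate it was higher by 2.2 but not called (limma adjusted p = 0.119). The mitochondrial stress gene AT2G21640 was lower at -1.08 (SE 0.17), the thylakoid calcium-sensing protein CaS at -0.80 (SE 0.10) and the light-harvesting protein LHCB4.3 at -0.72. Also lower were AT4G17250 (-1.41, or -1.72 with no offset and -0.93 with 4 times the offset), the GDSL-type lipase AT4G28780 (-1.01), the copper amine oxidase AT3G43670 (-0.88) and AT1G73120 (-0.82). The 4 measured nuclear photosynthesis genes, LHCB4.3 among them, were not lower as a group. Their median centred log2 signal was 0.03 ± 0.07 in Zat12 and -0.03 ± 0.06 in wildtype (SD, n = 3 per group).

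Plastid-encoded genes were higher as well. Of the 56, 27 were higher and 0 lower, or 48 and 0 adjusted over the list alone, led by psaA at 3.58 (SE 0.45), psbC at 2.71 (SE 0.39), petL at 2.59 (SE 0.37), psaB at 2.25 (SE 0.29), psbT at 1.90 (SE 0.34) and atpH at 1.89 (SE 0.32). The list had an adjusted p = 4.25e-51 with limma's camera and an adjusted p = 0.272 with an estimated correlation. The untreated wildtype arrays, with their low plastid medians and the lowest mean 25S control signal, were the reference here. With that signal as a covariate 4 of the 56 were called, and their median was 0.661, from 0.943 without it. Not called were atpH, at 1.16 (limma adjusted p = 0.106), and psbT, which stayed at 1.88 (0.0809).

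In all 99 probe sets were higher and 68 lower, 1.22% of those tested, and 31 and 17 with the 25S control as a covariate. With that covariate AT1G73120 (-0.63, from -0.82, limma adjusted p = 0.089), UGT78D1 (-0.98, from -0.83, 0.0589) and AT2G39500 (-0.88, from -1.12, 0.352) were not called, although the difference of UGT78D1 did not shrink. Some large differences were on probe sets with no gene in the annotation, and 4 were chosen after their values were seen. The probe set 254098_at was lower at a log2 difference of -5.70 (SE 0.41), with 74.6 ± 50.6 (SD, n = 2) in Zat12 against 3602 ± 412 (SD, n = 3) in wildtype, and 251733_at at -1.73 (SE 0.25). The probe sets 247655_at and 266165_at were higher by 3.43 (SE 0.12) and 2.03 (SE 0.10). Which genes these probe sets measure was not known here, so whether one of them measures the over-expressed gene is open.

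The limits lay in single arrays: the 99 became 46 without wildtype replicate 1, 168 without wildtype replicate 3, 26 without Zat12 replicate 1 and 45 without Zat12 replicate 2, and the 68 became 24 without wildtype replicate 1, 42 without wildtype H2O2 replicate 3, and 16, 25 and 33 without Zat12 replicates 1, 2 and 3. With no filter on low signals 37 probe sets were higher and 23 lower, and with no mean-variance trend 40 and 21. AT4G17250 was not called with no filter (0.0567) or in the fit on the compared arrays only (0.107), nor were AT2G04050 (0.0672) and psbT (0.0601) with no filter. Without Zat12 replicate 1, psbT (adjusted p = 0.0853), atpH (0.0651), AT4G28780 (0.0676) and AT1G73120 (0.0519) were not called, and AT2G04050 was not called without wildtype replicate 1 (0.0509), Zat12 replicate 2 (0.0666) or Zat12 replicate 3 (0.0507). UGT78D1 (-0.83) and AT2G39500 (-1.12) were called by limma with all arrays; UGT78D1 was not called without wildtype replicates 1 (0.108) or 3 (0.0532) or Zat12 replicates 1 (0.149) or 3 (0.0974), and AT2G39500 without any of 8 arrays, with an adjusted p of up to 0.405 without Zat12 replicate 1.

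Further lists passed the test in this contrast with few called members. The detoxification list was called higher (limma's camera, adjusted p = 0.0225; adjusted p = 0.385 with an estimated correlation) with AT2G04050 as its 1 called member, or 2 adjusted over the list alone. The chaperone list was called higher (0.032; adjusted p = 0.385 with an estimated correlation) with AT5G37670 (0.71) called, or 2 adjusted over the list alone. Mitochondria-encoded genes were called higher (0.0423; adjusted p = 0.332 with an estimated correlation) with ccb382 (0.80) called, also adjusted over the list alone; the untreated wildtype arrays stood apart here too, with medians of these genes between -0.28 and -0.26 against -0.21 to 0.26 on the other 9 arrays. The thiol redox list was called lower (0.0442; adjusted p = 0.543 with an estimated correlation) with MSRB6 (-0.68), a methionine sulfoxide reductase, called, also adjusted over the list alone. The autophagy list was called lower (0.032; adjusted p = 0.581 with an estimated correlation) and the cold and abscisic acid list was called lower (0.0341; adjusted p = 0.385 with an estimated correlation), with 0 called members each, and 0 and 2 adjusted over the list alone. Each of these 6 list calls ended without wildtype replicate 2, with adjusted p between 0.108 and 0.243, and several also ended without other single arrays. The autophagy, thiol redox and cold list calls ended without Zat12 replicate 2 (camera adjusted p = 0.158, 0.158 and 0.0518), an array that the estimated correlation leaves out too. Without wildtype replicate 2, AT5G37670 (0.0666), ccb382 (0.0907) and MSRB6 (0.143) were not called either. With the 25S control as a covariate the autophagy list turned from lower to higher (adjusted p = 0.746), and the chaperone (0.198), thiol redox (0.746) and cold lists (0.464), AT5G37670 (0.198), ccb382 (0.342) and MSRB6 (0.519) were not called.

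**Figure D4:**
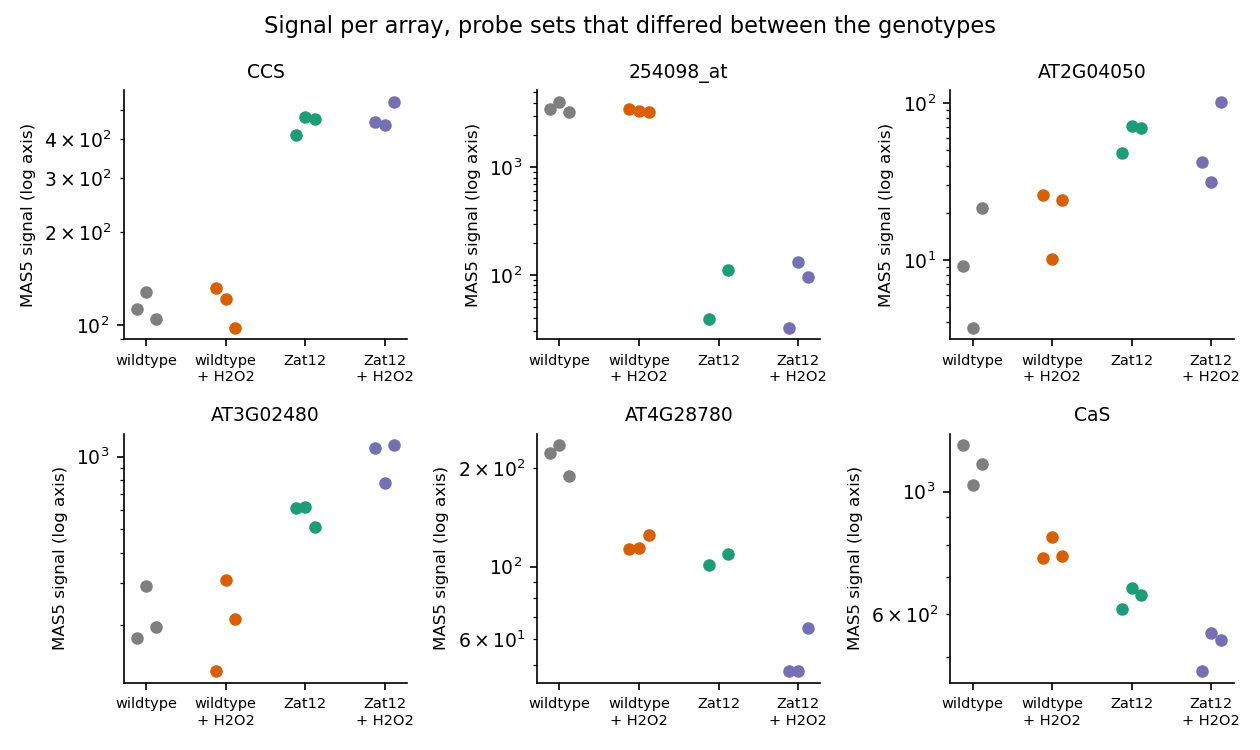
MAS5 signal (y axis, log scale, arbitrary units) of 5 genes and of 254098_at, a probe set without a gene name, on each array, by group (x axis); each point is 1 array, and probe sets empty on Zat12 replicate 2 have 2 points there. CCS lies near 450 in Zat12 and near 115 in wildtype, while 254098_at lies far lower in Zat12.

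The comparison of Zat12 with wildtype under H2O2 asked how the genotypes differ once treated. Among the named differences were those of AT4G36600, a late embryogenesis abundant protein that was higher in Zat12 by 2.39 (SE 0.43), ATOEP16-2, an outer plastid envelope protein, by 2.32 (SE 0.39), and the late embryogenesis abundant proteins AT3G02480 by 2.25 (SE 0.24) and AT5G44310 by 1.89 (SE 0.34). AT3G02480 had a signal of 993 ± 188 against 217 ± 90.5 (SD, n = 3 per group). CCS was higher by 2.01 (SE 0.13). Lower in Zat12 were the jacalin-type lectin AT1G52070 (-1.38), AT4G28780 (-1.10), the peroxidase AT2G37130 (-1.09), the aspartyl protease AT1G09750 (-1.07) and psbT (-1.39). The limma adjusted p of these 10 genes was between 6.35e-08 and 0.0352.

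Of the 14 chaperones and co-chaperones 5 were higher in treated Zat12 than in treated wildtype and 0 lower, or 9 and 0 adjusted over the list alone, with a median of 0.40 (limma's camera, adjusted p = 2.13e-06; adjusted p = 0.115 with an estimated correlation). Hop3, a co-chaperone that links Hsp70 and Hsp90, went from 94.7 ± 5.22 in treated wildtype to 183 ± 26.1 in treated Zat12 (SD, n = 3 per group), a difference of 0.92 (SE 0.17; adjusted p = 0.00716, and 0.0519 without Zat12 H2O2 replicate 3). The planned heat shock list was called higher with AT5G37670 (0.61) as its 1 called member, or 3 adjusted over the list alone (adjusted p = 0.0231; adjusted p = 0.259 with an estimated correlation). Of the 56 plastid-encoded genes 3 were lower, psbT, rps2 (-1.03) and psbZ, or 7 adjusted over the list alone (adjusted p = 1.08e-05, or 0.493 with an estimated correlation). With the 25S control as a covariate 10 of the 56 were called, with a median of -0.373 against -0.377 without it. The unnamed probe sets 254098_at (-5.44) and 247655_at (2.03) differed here too.

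In all 207 probe sets were higher and 191 lower, 2.92% of those tested. A fit of the treated arrays alone, without a block, called 525, and the replicate block on all 12 arrays called 465. With the replicate number as a block on the treated arrays alone, 533 were higher and 480 lower. Of these, 394 were among the 398 called on all 12 arrays without the block. The rise from 398 thus mixes the choice of arrays with the block. The counts without the block became 53 and 73 without wildtype H2O2 replicate 1, 129 and 99 without its replicate 2, 84 and 73 without Zat12 H2O2 replicate 1, 101 and 122 without its replicate 2, 67 and 67 without its replicate 3, and 328 and 302 without untreated wildtype replicate 2; without wildtype H2O2 replicate 3, 72 were lower. With the 25S control as a covariate they were 345 and 312, with no filter on low signals 131 and 121, and with no mean-variance trend 106 and 89. The calls of AT5G37670, psbT, rps2 and psbZ also ended when single arrays were left out, with adjusted p of up to 0.143, 0.182, 0.0943 and 0.159, and the heat shock list without wildtype H2O2 replicate 2 (0.0608) or Zat12 H2O2 replicates 1 (0.0628) or 3 (0.109).

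**Figure D5:**
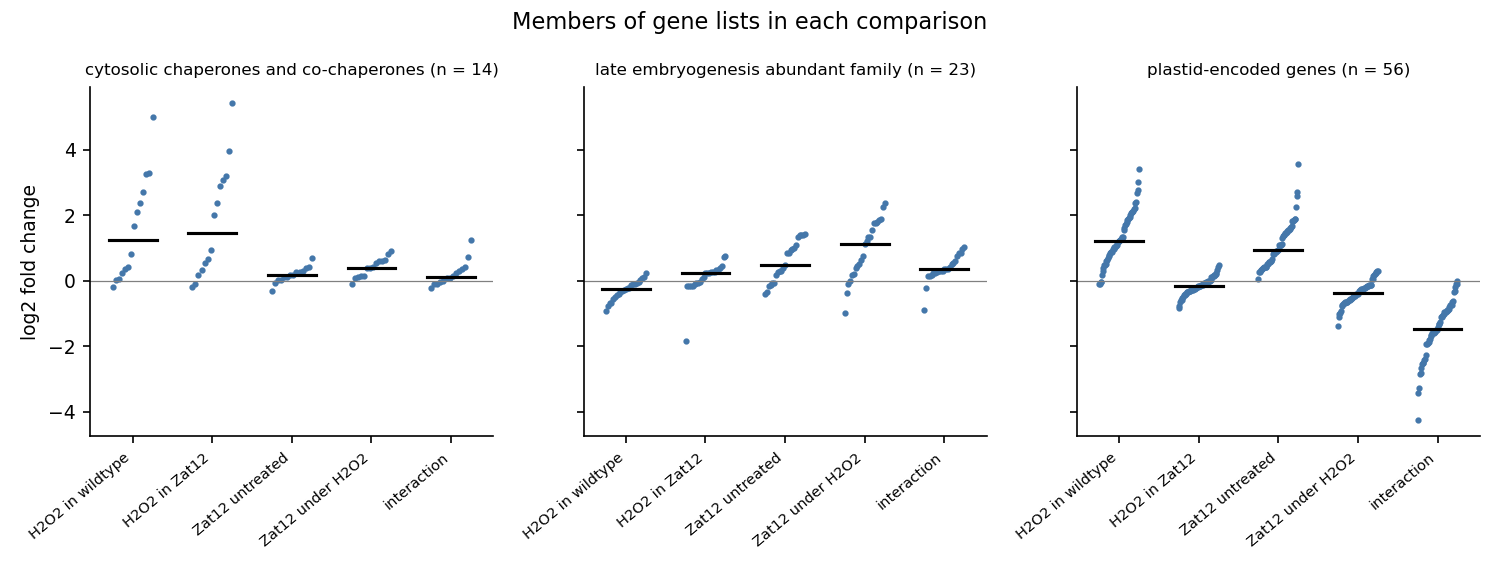
Log2 fold change (y axis) of each measured member of 3 gene lists in each of the 5 contrasts (x axis); points are genes, sorted within a contrast, and black bars are medians. The chaperone medians are 1.25 and 1.46 for H2O2 in wildtype and Zat12, the plastid median is 1.21 for H2O2 in wildtype and -1.46 for the interaction, and the late embryogenesis abundant list, chosen after values were seen, has a median of 1.13 for Zat12 under H2O2.

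The interaction asked whether H2O2 acts differently in the genotypes. Most of the called probe sets were plastid-encoded, and the H2O2 response was lower in Zat12 than in wildtype for psaA by a log2 difference of -4.27 (SE 0.63), psbC by -3.42 (SE 0.55), psbT by -3.28 (SE 0.48), petL by -2.85 (SE 0.53) and psaB by -2.83 (SE 0.41). psaA had signals of 46.6 ± 46.1 and 408 ± 134 in untreated and treated wildtype, and 457 ± 154 and 250 ± 76.6 in untreated and treated Zat12 (SD, n = 3 per group). By limma 0 probe sets had a larger and 15 a smaller response in Zat12, with 971 at an unadjusted p below 0.05, and 12 of the 15 were plastid-encoded. The other 3 were unnamed, among them 247655_at (-1.41), whose gene was not known here. The plastid list was called (limma's camera, adjusted p = 2.75e-62; adjusted p = 0.144 with an estimated correlation), with 0 higher and 49 lower adjusted over the list alone. With the 25S control signal as a covariate 8 probe sets were called, 5 of them plastid-encoded, and petL was not, at -2.56 (limma adjusted p = 0.231). The median of the 56 plastid-encoded genes was then -0.975, from -1.46.

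The UDP-glycosyltransferase list (median -0.24) was called lower by limma's camera (adjusted p = 0.00189; adjusted p = 0.429 with an estimated correlation), and so were mitochondria-encoded genes (median -0.44; adjusted p = 0.0101; adjusted p = 0.171 with an estimated correlation), whose medians were lowest on the 3 untreated wildtype arrays. The autophagy list (median 0.29) was called higher (adjusted p = 0.00575; adjusted p = 0.458 with an estimated correlation), and so was the chaperone list (median 0.12; adjusted p = 0.0351; adjusted p = 0.429 with an estimated correlation). None of these 4 lists had a called member; adjusted over the list alone, 2 UDP-glycosyltransferases and 1 mitochondrial gene were lower, and 1 chaperone was higher. With the 25S control as a covariate the autophagy list was not called (0.75). The 15 called probe sets became 10, 7 and 48 without wildtype replicates 1, 2 and 3, of which 2, 0 and 4 had a larger response in Zat12. They became 7 and 9 without wildtype H2O2 replicates 1 and 2, all with a smaller response, 10 without Zat12 replicate 2, of which 1 was larger, and 25, 7 and 6 without Zat12 H2O2 replicates 1, 2 and 3, of which 1, 0 and 0 were larger. With no filter on low signals or with no mean-variance trend 3 probe sets were called, and none of the 5 named genes was (limma adjusted p between 0.118 and 0.193, and between 0.0583 and 0.19). The calls of petL and psbC ended without single arrays (adjusted p of up to 0.175 and 0.0771), as did those of the mitochondrial (up to 0.0855), autophagy (up to 0.0631) and chaperone lists (up to 0.179).

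Finally, the changes in untreated Zat12 were set beside the H2O2 response of wildtype, to ask whether over-expression moves the genes that the treatment moves. Both contrasts use the untreated wildtype arrays. Across probe sets r was 0.278, where unchanged groups against the same controls gave 0.483 in simulation, and the covariance was 0.0426 against a simulated 0.0174, a difference of 0.0252. Without plastid-encoded probe sets r was 0.241 and the covariance 0.0346. In both contrasts 48 probe sets were higher and 35 lower, and 4 went in opposite directions. Independent lists would share 9.5 and 8.42. Unchanged groups against the same controls shared 0 and 0 in simulation, but so did unchanged groups that share no arrays. That simulated count therefore does not show how many shared calls the common controls add. Without the plastid-encoded probe sets 21 were higher and 35 lower in both, where independent lists would share 6.7 and 8.45. The 3 wildtype arrays cannot be split into parts of 2, so part of the excess may come from the shared controls. Without wildtype replicate 3 the covariance was 0.0666. Untreated and treated Zat12, each against its own wildtype, shared 39 higher and 34 lower probe sets, where independent lists would share 1.5 and 0.952 (r = 0.356).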

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

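The tests on the plastid-encoded genes and the comparison of the 25S control were chosen after those patterns were seen; the counts over other splits of the arrays were planned, except that the 2 counts over splits that part the same-numbered treated pairs were chosen after the results were seen.

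The H2O2 response of 15 probe sets differed between the genotypes in the test of the interaction, led by psaA (-4.27), psbC (-3.42), psbT (-3.28), petL (-2.85) and psaB (-2.83). The same test on gene lists gave adjusted p of 2.75e-62 for plastid-encoded genes, 0.00189 for UDP-glycosyltransferases, 0.00575 for the autophagy list, 0.0101 for mitochondria-encoded genes and 0.0351 for chaperones with limma's camera. With an estimated correlation none of these 5 calls held (adjusted p = 0.144, 0.429, 0.458, 0.171 and 0.429). Signals outside the comparisons stood out as well: the ubiquitin control probe set was 1.52-fold higher on the 6 treated than on the 6 untreated arrays (two-sided exact permutation p = 0.00216). That test was not in the design fixed beforehand, and its p is not adjusted for the other control probe sets. The 25S ribosomal RNA control was 3.17-fold higher on average on the other 9 arrays than on the 3 untreated wildtype arrays, which had been seen to stand apart, although wildtype replicate 3 (125.3) lay above Zat12 replicate 3 (96.3).

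Plastid-encoded genes were lower on the untreated wildtype arrays than in the other 3 groups, and so appear in each contrast that uses those arrays. Less green tissue in untreated wildtype is argued against by the few nuclear genes measured. The shift of the other 3 groups against it was 1.01 for the plastid genes. For the 4 measured of 28 planned nuclear photosynthesis genes it was 0.103 (SD over members 0.362, from -0.549 to 0.264). LHCB4.3, 1 of the 4, was itself lower in untreated Zat12, so the 4 are not a clean marker of tissue. RNA without poly(A) tails that entered the labelling in amounts that differ between arrays may contribute and stays open: over the 12 arrays, as deviations from group means, the plastid median and the log2 25S control signal had r = 0.877 (exact permutation p within groups 0.0278, 0.0556 adjusted over 2 relations, with same-numbered treated arrays kept together, and 0.0556, 0.111 adjusted, with those of all 3 other groups kept together, whose replicate 3 was lowest in both measures; rho = 0.86, exact permutation p = 0.0278; r = 0.794 without the 2 farthest arrays). With that control as a covariate the shift against untreated wildtype stayed above 2 standard errors in 2 of the 3 groups. It was 0.706 (SE 0.172) in treated wildtype and 0.626 (SE 0.151) in untreated Zat12, from 1.3 and 1.07 (SE 0.233 each). In treated Zat12 it was 0.326 (SE 0.171), from 0.917, less than 2 standard errors. The control is 1 probe set whose own error the fit does not count, and such error can leave part of a shift in place. RNA without poly(A) tails as the whole cause therefore stays open in all 3 groups. Loss of 5' RNA stays open (actin ratio, r = -0.542, exact permutation p = 0.208, rho = -0.427, p = 0.292, and r = -0.41 without the 2 farthest arrays). The GAPDH ratio gave no sign of it, at 0.751 to 0.867 on untreated wildtype and 0.741 to 0.866 on the other arrays. A biological difference in plastid transcripts between the groups stays open too and was not tested apart from these.

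In the interaction, 4 of 100 splits drawn from the 200 of the genotype labels, the real one included, gave at least 15 probe sets. Of the 80 splits that part the 3 same-numbered pairs of treated arrays, 5 did, the real one included, a share that is not under 0.05. The highest other split gave 766 in both counts. It exchanged the genotypes in 1 treatment only and so measures the genotype difference common to both treatments, a structure of the samples. Among the 80, splits with 230 and 15 probe sets did the same but for 1 untreated array of each genotype, and the last of the 5 gave 24. The count mixes that structure with chance, so it neither excludes chance alone nor shows it. For the 4 contrasts of 3 against 3 arrays, 1 of 10 splits, the real one, gave as many probe sets, which is too few splits for a share under 0.05. The real values were 2998, 2358, 167 and 398 for H2O2 in wildtype, H2O2 in Zat12, Zat12 untreated and Zat12 under H2O2, and the highest others 0, 1, 2 and 1. For Zat12 under H2O2, whose arrays met the pairing rule, 4 of the splits part all 3 same-numbered pairs. The highest of these other than the real one gave 0.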

How the results depend on the processing

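The fit without plastid-encoded probe sets, the fit with the 25S control as a covariate and the block on the treated arrays were chosen after the data were seen. Of 101 results, 72 kept their direction and their side of the threshold under every alternative in which they were tested. The 101 cover the genes with the largest changes, called members of called lists, and the unnamed probe sets picked for untreated Zat12. They leave out genes named only from lists that were not called or were chosen after values were seen. With the 60th percentile filter 68 of the 101 had a value, and with no offset 97, since the others did not pass the filter. Of the 2498 values of the 101 results under alternatives, 171 were not past the threshold and 0 had the other sign. Neither quantile nor median scaling moved the share of higher calls by more than 10 percentage points. Signal over background limits low probe sets, and the causes of the changes below were not tested. Leaving out arrays lowers power, and changing the filter changes the number of tests. Lower power does not account for counts that rose, such as Zat12 under H2O2 from 398 to 630 without untreated wildtype replicate 2. The interaction likewise rose from 15 to 48 without wildtype replicate 3.

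Counts of probe sets are given as higher and lower. With no filter they were 37 and 23 for Zat12 untreated, 131 and 121 for Zat12 under H2O2, and 3 lower for the interaction. With no mean-variance trend they were 40 and 21, 106 and 89, and 3 lower. With only the compared arrays, 32 were lower in Zat12 untreated. At an adjusted p under 0.01, 772 were lower for H2O2 in wildtype and 605 for H2O2 in Zat12, with 30 and 17 for Zat12 untreated, 53 and 49 for Zat12 under H2O2 and 6 lower for the interaction. With a change of at least 2-fold they were 608 and 110, 550 and 114, 53 and 12, and 45 and 24 for the 4 contrasts of 3 against 3 arrays. The interaction, with 0 higher, had 1 with median centring, 2 with 4 times the offset and 1 with the 60th percentile filter. Without plastid probe sets, 62 were higher in Zat12 untreated and 3 lower in the interaction. With the 25S covariate the counts were 869 and 820 for H2O2 in wildtype, 31 and 17 for Zat12 untreated, 345 and 312 for Zat12 under H2O2, and 8 lower for the interaction.

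With each array left out, counts of lower probe sets ranged from 1074 to 1667 for H2O2 in wildtype and from 825 to 1519 for H2O2 in Zat12. In Zat12 untreated the ranges were 26 to 168 higher and 16 to 74 lower, in Zat12 under H2O2 53 to 328 and 67 to 302, and in the interaction 0 to 4 and 6 to 44. The covariance of H2O2 in wildtype and Zat12 untreated ranged from 0.0401 to 0.0666. The covariance of the H2O2 responses, 0.278, was 0.297 with no offset, 0.233 with 4 times the offset, 0.222 with no filter and 0.316 with the 60th percentile filter, and their r was 0.682 with no filter.

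The number of lists called was 8, 5, 7, 3 and 5 in the order of the contrasts. With an estimated correlation, in a run that also left out Zat12 replicate 2, it was 2, 3, 0, 0 and 0. In that run 23 of 28 list calls ended. Of these, the autophagy, thiol redox and cold list calls in Zat12 untreated had also ended at the preset correlation without that array. Their camera adjusted p was 0.158, 0.158 and 0.0518 there. The test fry asks whether members change at all, and camera whether they change more than other probe sets. Their numbers of lists are therefore not like for like. With fry, also run without that array, the number of lists called was 17 for H2O2 in wildtype and 13 for H2O2 in Zat12. It was 0 for Zat12 untreated and 0 for the interaction, and 13 of the 28 calls ended. With camera it was 10 for H2O2 in Zat12 with no filter. With the 60th percentile filter it was 5, 2, 3 and 3 for H2O2 in wildtype, H2O2 in Zat12, Zat12 untreated and the interaction. With the 25S covariate it was 8 for H2O2 in Zat12 and 3 for Zat12 untreated. With single arrays left out it ranged from 1 to 7 for Zat12 untreated and from 3 to 7 for the interaction.

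The adjusted p with an estimated correlation, for H2O2 in wildtype, was 0.15 for plastid genes, 0.124 for detoxification, 0.0625 for WRKY factors, 0.268 for UDP-glycosyltransferases, 0.124 for calmodulin-like proteins and 0.15 for U-box ligases. For H2O2 in Zat12 it was 0.158 for detoxification and 0.0733 for calmodulin-like proteins. For Zat12 untreated it was 0.272 for plastid genes, 0.385 for detoxification, chaperones and the cold list, 0.581 for autophagy, 0.332 for mitochondrial genes and 0.543 for thiol redox. For Zat12 under H2O2 it was 0.115 for chaperones, 0.493 for plastid genes and 0.259 for heat shock proteins. For the interaction it was 0.144 for plastid genes, 0.429 for UDP-glycosyltransferases and chaperones, 0.458 for autophagy and 0.171 for mitochondrial genes. With fry it was, for Zat12 untreated, 0.0875 for plastid and mitochondrial genes, 0.235 for detoxification, 0.17 for chaperones, 0.473 for autophagy, 0.171 for the cold list and 0.382 for thiol redox. For Zat12 under H2O2 fry gave 0.344 for plastid genes, and for the interaction 0.0784 for plastid and mitochondrial genes, 0.301 for UDP-glycosyltransferases, 0.553 for autophagy and 0.365 for chaperones.

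Other settings ended few list calls. For Zat12 untreated, thiol redox had an adjusted p of 0.0574 with quantile normalization, 0.134 with the 60th percentile filter and 0.051 with no trend. For Zat12 under H2O2, heat shock proteins had 0.0503 with no offset and 0.145 with that filter. For the interaction, chaperones had 0.0713 with no offset and 0.0745 with that filter, and with no filter UDP-glycosyltransferases had 0.072 and mitochondrial genes 0.062. With the 25S covariate, UDP-glycosyltransferases (0.0974) and U-box ligases (0.095) were not called for H2O2 in wildtype, nor the cold list (0.464), chaperones (0.198) and thiol redox (0.746) for Zat12 untreated, nor autophagy (0.75) for the interaction. Autophagy in Zat12 untreated turned from lower to higher with that covariate (0.746).

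With single arrays left out, the adjusted p for Zat12 untreated ranged from 0.0174 to 0.117 for mitochondrial genes, 0.00477 to 0.243 for autophagy, 0.0107 to 0.108 for chaperones, 0.00485 to 0.214 for thiol redox, 0.00115 to 0.108 for detoxification and 0.0213 to 0.186 for the cold list. For H2O2 in wildtype it ranged from 0.0338 to 0.0703 for U-box ligases and from 0.0086 to 0.0567 for calmodulin-like proteins, and for Zat12 under H2O2 from 0.00418 to 0.109 for heat shock proteins. For the interaction it ranged from 0.000387 to 0.0631 for autophagy, 0.00592 to 0.179 for chaperones and 0.00347 to 0.0855 for mitochondrial genes.

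By the rule above the replicate numbers paired the treated arrays of the genotypes, though chance can meet that rule with 3 arrays per group. With the replicate block on those arrays only, 533 probe sets were higher and 480 lower in Zat12 under H2O2. No call of a named gene or list changed there. Without the block the same arrays gave 525 called probe sets, against 398 in the fit of all 12 arrays. No other 2 groups had every same-numbered pair over 0.1, but untreated and treated Zat12 came near, at 0.0789 to 0.232 against -0.133 to 0.0127 for different numbers. With the replicate block on all arrays 2539 probe sets were called for H2O2 in Zat12, 2307 of them among the 2358 called without it. Of all 18 same-numbered pairs 7 had a correlation of deviations over 0.1 (-0.254 to 0.232, against -0.133 to 0.214 for different numbers), and 7 of 12 arrays correlated best with their own number. With the replicate block on all arrays the U-box list for H2O2 in wildtype had an adjusted p of 0.0637, and for Zat12 untreated the cold list had 0.0544, mitochondrial genes 0.0621 and thiol redox 0.0621, which left 4 lists called there. The block ended 3 of 101 calls of named genes and moved no count of probe sets by over 1.5 times.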

Other observations

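The lists in the next 2 paragraphs were chosen after values were seen and were not run under the alternatives; the tests on them and on the chaperones were written before their results, while the widened errors of the late embryogenesis tests and the tests without leading or named members were chosen after them.

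Late embryogenesis abundant proteins, hydrophilic proteins of maturing seeds and of tissues short of water, were higher in Zat12 than in wildtype under H2O2. Of 23 measured, 14 were higher and 0 lower, or 17 and 1 adjusted over the list alone, with a median log2 difference of 1.13 (limma's camera, adjusted p = 1.25e-17 over the 3 lists; adjusted p = 0.0252 with an estimated correlation), among them AT5G66780 (1.85), LEA18 (1.78) and AT3G15670 (1.77). Without treatment 6 were higher and 0 lower, or 11 and 2 adjusted over the list alone, with a median of 0.49 (adjusted p = 9.35e-08; adjusted p = 0.376 with an estimated correlation), including LEA18 (1.41). Of the 17 left without the 6 members that a rule had named in any contrast, 11 were higher under H2O2 and 0 lower (adjusted p = 8.55e-17; adjusted p = 0.032 with an estimated correlation). The 1 measured gene of the 15 planned seed and embryo markers, the isocitrate lyase ICL, was higher in Zat12 under H2O2 by 0.63 (SE 0.14, limma adjusted p = 0.0208), with a difference of 0.46 (SE 0.14, adjusted p = 0.146) without treatment.

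Class III peroxidases, which act in the cell wall, were lower in treated Zat12 than in treated wildtype for 7 of 31 and higher for 0 (limma's camera, adjusted p = 9.48e-08; adjusted p = 0.0252 with an estimated correlation), led by AT2G37130 (-1.09), AT4G30170 (-0.84) and AT5G40150 (-0.78). Of the 27 left without the 4 members already named, AT2G37130 among them, 5 were lower and 0 higher (adjusted p = 8.2e-06; adjusted p = 0.032 with an estimated correlation). Under H2O2, 12 fell and 3 rose in Zat12 (adjusted p = 8.26e-04; adjusted p = 0.162 with an estimated correlation), a call that ended without those 4 (adjusted p = 0.071), and 11 fell and 5 rose in wildtype (adjusted p = 0.178). The interaction of this list had an adjusted p = 2.07e-05, and an adjusted p = 0.0891 with an estimated correlation; without those 4 these were 5.25e-04 and 0.128. Of 8 small heat shock proteins 4 were higher in treated Zat12 and 0 lower (adjusted p = 2.01e-06; adjusted p = 0.0252 with an estimated correlation), led by AT2G29500 (0.85) and AT1G54050 (0.64); of the 4 left without members already named 3 were higher (adjusted p = 9.24e-05; adjusted p = 0.032 with an estimated correlation).

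A hypothesis for the late embryogenesis abundant proteins is that H2O2 raises their difference between the genotypes. More seed or embryo tissue in Zat12 would give the same difference with and without treatment, and it stays open: the medians differed by 0.639, less than 2 standard errors (SE 0.601, resampled over members and widened by their estimated correlation of 0.409), and by 0.348 (SE 0.47) without the 3 members that led the contrast before the family was chosen. The bound set beforehand, 2 standard errors of the mean paired difference (SE 0.0851), was wrong for this value, since it took the members as independent and belongs to another statistic. The interaction of the list was called with the preset correlation only (limma's camera, adjusted p = 5.73e-06; adjusted p = 0.101 with an estimated correlation), and limma called 0 of the 23 members in it, also adjusted over the list alone, with 3 at an unadjusted p below 0.05. A larger H2O2 response of Zat12 as a whole was not seen: the slope of the Zat12 on the wildtype response over 3700 called probe sets was 0.996. A larger response needs a slope above 1, but no spread of the slope was computed. The family itself does not decide this, since its median change under H2O2 in wildtype was -0.246 (SE 0.252 widened in the same way).

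For the chaperones, the question was whether a larger response of Zat12 as a whole accounts for the difference between the genotypes. The slope of the Zat12 on the wildtype response over called probe sets, 0.996, showed no such larger response, though no spread of it was computed. The other 911 probe sets that rose in both had a median difference of 0.0329, and the list one of 0.116 (SE 0.137 widened by its correlation), so the test does not separate them.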
